A study of Mus musculus with 6 samples.

How the data were processed

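Ribosome-associated mRNA, 100 ng per sample per the labels, was hybridised to Affymetrix MoGene-2_0-st arrays, 3 from sham-operated control mice and 3 from mice taken 24 h after tMCAO. Per the labels, 6 mice were used per group with 3 biological replicates and no technical replicates. How the mice were distributed over the arrays is not given in the sources used here. The labels describe the animals both as males only and as an equal mix of sexes, so sex was not used as a factor.

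The value table as deposited holds, for each of 41345 transcript clusters (the probe groups of a gene on the array) and each array, a log2 signal that the authors had already summarised and scaled. The series' design text names Transcriptome Analysis Console 3.0 as the processing software, and the file headers name the array annotation na36 on mm10. The summarisation and normalization methods and the authors' test are not given in the sources used here. A second table, deposited by the authors as a workbook, compares stroke with control by cluster. Per the file headers it gives a group average in log2 units for each group, a fold change, which is a score written as minus the inverse fold where stroke is lower, and a p-value with its false discovery rate adjustment. Its averages equalled Tukey biweights (tuning constant 5, epsilon 1e-04) of the value table within 0.0051 for 100% of its clusters. The logarithm of its p-values correlated with that of limma's moderated p-values at r = 0.999785 across clusters. All columns with values were used (0 left out). Array medians lay between 5.23 and 5.35, no detection calls were used, and the number of arrays limits the precision. A low control signal is therefore not shown to be above background, and folds hold for the signal as measured.

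Gene symbols were taken from the workbook. Of the 41345 clusters, 6873 were not in it, 2599 had no symbol and 1902 carried several symbols; these were left out of the gene comparison and are covered under the results singled out for a closer look. The remaining 29971 clusters covered 29458 genes, with the cluster of highest mean signal kept for each of 381 symbols with more than 1. No filter on dim clusters was used. Stroke was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05; calls of at least 2-fold were also counted. Gene coordinates are from the GRCm38 (mm10) annotation. The comparison, its alternatives, 32 gene lists with 598 members and the rule for naming genes were fixed before the data were examined.

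Of the list members, 583 were measured, with 1 symbol updated through its synonym (Lilrb4 to Lilrb4a). The others have no cluster of their own, since their clusters also carry other symbols; among them are Gfap, Glul, Cd74, H2-K1, H2-D1 and the beta globin genes. Each list with at least 5 measured members (31 lists) was tested against the other genes with camera at a preset correlation of 0.01, adjusted over the lists, and again with camera at an estimated correlation. Separately, fry tested whether the genes of each list moved one way on balance, without comparing them with other genes. Members were counted over all genes and when adjusted over the list alone. The report names the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with separated groups; up to 4 members past the threshold of each list with the largest change, or the 2 brightest members where none passed; and Itgam, Rpl10a, Srsf3, P2ry12, Tmem119, Cx3cr1, Il1b, Tnf, Ccl2 and the sex-linked genes whatever their result. Unnamed gene models, small RNAs, olfactory and vomeronasal receptors and antigen receptor segments were passed over among the largest changes but stay in the counts. Some genes that the rule names are not reported here.

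Alternatives were the replicate number as a block, quantile normalization, centring each array on its median, filters at the 25th percentile and at the median of signal, trend and robust eBayes, array weights, the mean over a symbol's clusters, a test without moderation, that test with an unadjusted p under 0.05 and at least 2-fold, and leaving out each array in turn. Leaving out both arrays numbered 2 was added after the data were seen. The labels do not say that same-numbered arrays share a litter, day or batch. As a check, the deviations of control and stroke arrays from their group means were correlated across genes, which are not independent. Same-numbered arrays gave r = 0.299, 0.576 and 0.39, and in 3 of 3 cases an array correlated best with its own number. Unlike numbers gave r from -0.46 to 0.237. The 3 deviations of a group sum to 0, so the 3 matches are not independent and do not establish a pairing. As a precaution, the blocked result is given where it ends the call of a gene named in the text.

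The procedure was tested on simulated data with 29458 genes, of which 200 were changed. It called 66% of genes changed 2-fold and 100% of those changed 4-fold, 5.14% of the calls were unchanged genes, and 100% of called changed genes had the right sign. A simulated list of 25 genes shifted by 0.5 (log2) had an adjusted p of 1.51e-25, and 0 of 20 unshifted lists passed (camera). The simulated noise was drawn independently for each gene. The simulation therefore does not show how correlation between genes affects the calls, above all those of lists. Its noise used limma's moderated variances, which lie closer together than the genes' own. The shares of calls may thus look better than they are for the real arrays. Tests between sets of genes used 100000 permutations, two-sided.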

Results

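Ribosome-bound mRNA was profiled on 6 Affymetrix MoGene-2_0-st arrays from brains of transgenic mice aged 2 to 3 months. There were 3 arrays from sham-operated controls and 3 from mice taken 24 h after transient middle cerebral artery occlusion (tMCAO). In this model, blood flow through a main brain artery is stopped and then restored. The mice carried a Flag- and EGFP-tagged ribosomal protein RPL10a driven by the CD11b promoter, which is active in microglia and other myeloid cells. Messenger RNA was taken from the tagged ribosomes by translating ribosome affinity purification (TRAP). The labels give 6 mice per group and 3 biological replicates, without saying how the mice were distributed over the arrays. Array medians over all transcript clusters lay between 5.23 and 5.35 on the log2 scale, and the number of arrays limits the precision of every value. Pearson correlations across genes ranged from 0.980 to 0.994 between pairs of arrays. The arrays numbered 2 of both groups stood apart from the other 4 along the first principal component, at 48.89 for control and 34.61 for stroke against -14.44 to -26.61 for the others, and this component held 45.1% of the variance.

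The comparison of stroke with control asks which mRNAs in the purified RNA changed within 24 h of the occlusion. Mean signal over the 6 arrays was 11.23 for the neuron, 9.78 for the oligodendrocyte and 8.98 for the astrocyte marker list. It was 7.61 for the homeostatic microglia list. The lists of these other cell types thus lay above the microglia list and above the array medians. Their signal argues that RNA of such cells was part of the purified RNA. Signals of different probes do not give its share, and whether it came from untagged cells was not tested. No array of unpurified RNA was compared, so a change cannot be placed in the tagged cells alone. Lilrb4a, an inhibitory immune receptor, rose 31.4-fold, from 4.76 ± 0.95 to 9.74 ± 0.45 (log2 signal, SD, n = 3 arrays per group; adjusted p = 0.00509). Its log2 difference of 4.97 was 4.19 without both arrays numbered 2, an alternative chosen after the data were seen. Ccl3, a chemokine that attracts monocytes and lymphocytes, rose 16.0-fold from 5.60 ± 0.26 to 9.60 ± 0.13 (adjusted p = 0.00025). Hmox1, the heme oxygenase that degrades heme, rose 12.1-fold from 5.78 ± 0.41 to 9.37 ± 0.54 (adjusted p = 0.00474).

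The other genes with the largest rises were Serpina3n, a secreted serine protease inhibitor, 9.77-fold from 8.31 ± 0.51 to 11.60 ± 0.41; Ccl12 and Ccl2, both ligands of the monocyte receptor CCR2, 9.15-fold and 7.77-fold; and Timp1, an inhibitor of matrix metalloproteinases, 9.15-fold. Ms4a6d, of the MS4A family of membrane proteins, rose 7.76-fold, Tgm1, a transglutaminase that cross-links proteins, 7.49-fold, and Lcn2, a lipocalin that binds iron-carrying siderophores, 7.08-fold. Their adjusted p values lay between 0.000614 and 0.00509. No detection calls were used, so low control signals, such as those of Ms4a6d (3.65 ± 0.23) and of Lilr4b (3.17), are not shown to be above background, and the folds hold only for the signal as measured. On GRCm38 (mm10), Ccl2 (82035577 to 82037452), Ccl12 (82101845 to 82103399) and Ccl3 (83647843 to 83649378) lie on chromosome 11. Lilrb4a lies on chromosome 10 (51490898 to 51496613), Hmox1 on chromosome 8 (75093618 to 75100593), Serpina3n on chromosome 12 (104406646 to 104414334) and Timp1 on chromosome X (20870166 to 20874737). Ms4a6d is at 11586606 to 11604804 of chromosome 19, Tgm1 at 55700009 to 55713921 of chromosome 14, and Lcn2 at 32384637 to 32387739 of chromosome 2. Lilrb4a and Lilr4b (4.32-fold higher), and Ms4a6d and Ms4a6c (2.82-fold higher), are closely related genes, and the probes of each may also have bound transcripts of the other; Lilr4b and Ms4a6c were named after their values were seen.

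**Figure D1:**
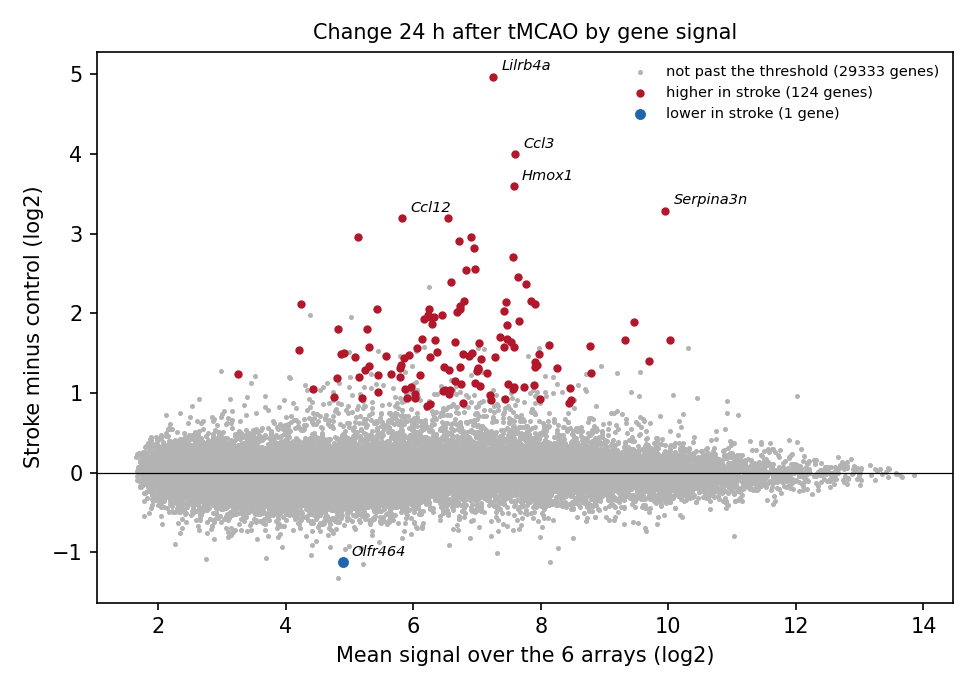
Each point is a gene, with its mean log2 signal over the 6 arrays on the horizontal axis and the log2 difference of stroke minus control on the vertical axis. Red points are the 124 genes higher and the blue point the 1 gene lower in stroke at an adjusted p under 0.05, and grey points are all other genes; the rises reach 4.97 (Lilrb4a), and the only fall past the threshold is Olfr464 at -1.12.

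In all, 124 of 29458 genes rose and 1 fell (limma, adjusted p under 0.05), and 109 of the 124 rose at least 2-fold. The median rise was 2.76-fold. With all 31 lists tested, 22 stood above and 2 below the other genes by camera with its preset correlation, and 15 above and 0 below with an estimated correlation. The gene that fell, Olfr464, an olfactory receptor gene named here only after its value was seen, fell by 1.12 on the log2 scale, from 5.45 ± 0.05 to 4.33 ± 0.17 (adjusted p = 0.0193). With the replicate number as a block, 153 genes rose, among them 110 of the 124, and 3 fell. Besides Olfr464 these were the adenosine receptor gene Adora2a (-0.82, blocked adjusted p = 0.045, 0.336 without the block) and the unnamed gene model Gm5449 (-0.94, blocked adjusted p = 0.0487). Both were also named after their values were seen. In all 125 genes, the 3 stroke values lay on the same side of all 3 control values, which follows largely from choosing them by these same values. Over all genes this was so for 11.2%, against 10% by chance. At an unadjusted p under 0.05, 1086 genes were higher and 611 lower, against 1473 in either direction by chance. Leaving out a single array gave 25, 73 and 40 higher genes without control replicates 1, 2 and 3, and 28, 63 and 29 without stroke replicates 1, 2 and 3. Not all of these were among the 125: without control replicate 2, 69 of 74 called genes were. Olfr464 stayed past the threshold only without control replicate 2. A test of each gene on its own spread, without limma's moderation, gave 0 genes after adjustment. At an unadjusted p under 0.05 and at least 2-fold it gave 163 higher and 3 lower genes, of which 110 were among the 125.

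**Figure D2:**
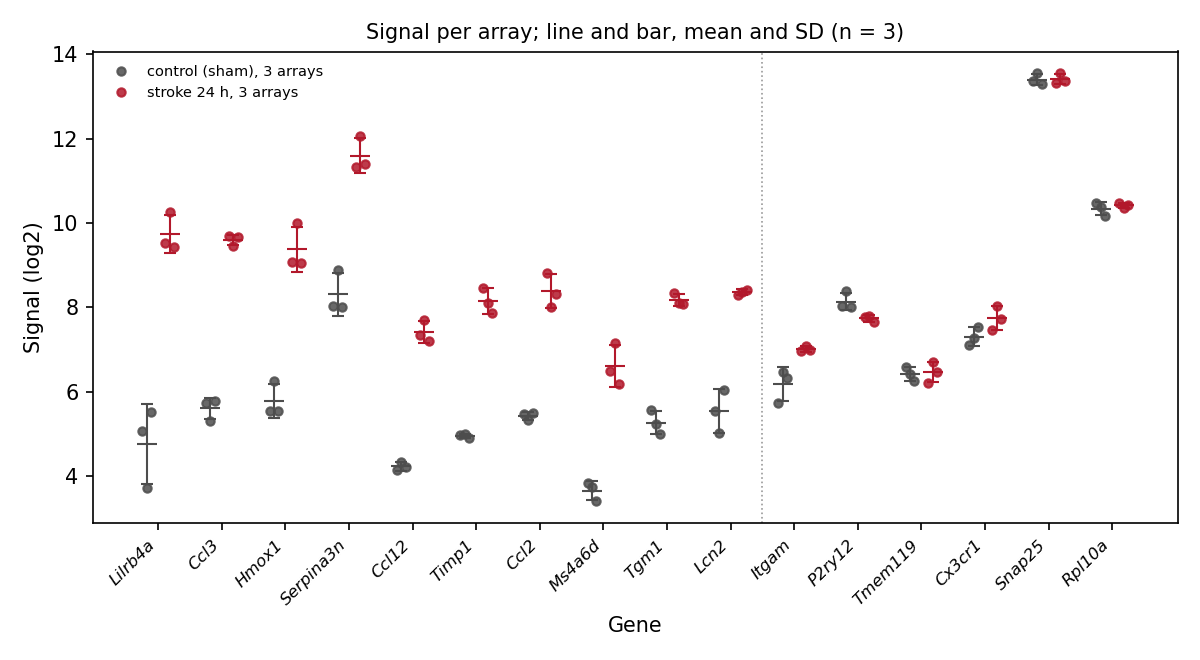
Log2 signal of each array for 16 genes, control arrays in grey and stroke arrays in red, with the mean and SD of the 3 arrays as a horizontal line and bar. The 10 genes left of the dotted line are those with the largest rises, from 2.82 (Lcn2) to 4.97 (Lilrb4a) on the log2 scale. In each the groups are separated, as the rule for naming them required. The 6 genes on the right did not pass the threshold.

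Among cytokines and chemokines, the secreted signals that recruit and activate immune cells, 10 of 30 measured genes rose, 0 fell and 20 did not pass, and 19 were higher when adjusted over the list alone. The list median was 0.95 on the log2 scale and the list stood above the other genes (camera adjusted p = 1.34e-29, and 0.00912 with an estimated correlation). Besides Ccl3, Ccl12 and Ccl2, the chemokine Ccl9 rose 6.53-fold, from 6.22 ± 0.46 to 8.92 ± 0.33 (adjusted p = 0.00792). Tumor necrosis factor (Tnf) rose 4.14-fold, from 5.22 ± 0.15 to 7.27 ± 0.49 (adjusted p = 0.0173). Interleukin 1 beta (Il1b) was 2.89-fold higher at 6.22 ± 0.55 against 4.68 ± 0.28, without passing the threshold (adjusted p = 0.0898). Ccl3, Ccl12, Ccl2 and Ccl9 stayed past the threshold without each of the 6 arrays in turn, while the adjusted p of Tnf reached 0.0846. In the same stroke arrays the marker lists of monocytes, neutrophils and astrocytes had medians of 0.33, 0.23 and 0.30 above control.

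Bcl3, a nuclear partner of NF-kB, rose 4.17-fold from 5.70 ± 0.24 to 7.76 ± 0.21, Cd14, a co-receptor for bacterial lipopolysaccharide, 3.65-fold, Tlr13, a sensor of bacterial ribosomal RNA, 2.76-fold, and Myd88, the adaptor of most Toll-like receptors, 2.15-fold. Of 28 genes of Toll-like receptor and NF-kB signalling, 5 rose and 23 did not pass, and 16 were higher when adjusted over the list alone (median 0.53; camera adjusted p = 1.63e-24, and 0.00912 with an estimated correlation). Of 17 genes of complement and Fc receptors, 4 rose and 13 did not pass, and 14 were higher when adjusted over the list alone (median 0.85; camera adjusted p = 1.54e-22, and 0.0168 with an estimated correlation). These were C3ar1 and C5ar1, receptors of complement fragments, at 4.25-fold and 2.33-fold, the high-affinity IgG receptor Fcgr1 at 2.17-fold and the complement component C4b at 2.06-fold. Among 25 genes of the type I interferon response, 4 rose and 21 did not pass, and 14 were higher when adjusted over the list alone (median 0.48; camera adjusted p = 3.18e-24, and 0.00912 with an estimated correlation). Ifitm3, which restricts virus entry, rose 3.16-fold from 8.48 ± 0.25 to 10.14 ± 0.24, Ifi44 rose 2.96-fold, the ubiquitin-like modifier Isg15 2.83-fold, and Bst2, which tethers virus particles, 1.98-fold (adjusted p = 0.0496, and 0.0666 with the replicate block). Of these 12 genes, Bcl3 alone stayed past the threshold without each of the 6 arrays in turn, and all 12 stayed higher in stroke.

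The genes used to recognise microglia at rest did not pass the threshold. Of 23 homeostatic microglia genes, 0 rose and 0 fell over all genes tested (limma; 2 were higher when adjusted over the list alone), with a median of 0.07. P2ry12, a purinergic receptor of resting microglia, was at 8.13 ± 0.21 in control and 7.74 ± 0.08 in stroke (adjusted p = 0.757). The values were 6.41 ± 0.17 and 6.46 ± 0.25 for Tmem119 and 7.30 ± 0.22 and 7.74 ± 0.29 for the fractalkine receptor Cx3cr1 (adjusted p = 1 and 0.865), and the brightest members, Cst3 and Mef2c, differed by -0.0069 and -0.14. The signal of these list members was not shown to come from microglia. RNA of other cells in the purified RNA could mask a change within microglia. The list's test was above the other genes at an adjusted p of 0.0429, which was an adjusted p = 0.397 with an estimated correlation and 0.507, 0.0661 and 0.19 without control replicate 1, control replicate 2 and stroke replicate 2. Of 22 genes of disease-associated microglia, a state described in neurodegeneration models, 4 rose and 18 did not pass, and 12 were higher when adjusted over the list alone (median 0.65; camera adjusted p = 4.44e-22, and 0.00912 with an estimated correlation). Besides Lilrb4a, they were Spp1 (osteopontin) at 5.15-fold, Ccl6 at 2.98-fold and the endosomal tetraspanin Cd63 at 2.14-fold (adjusted p = 0.0499, and 0.0781 with the replicate block). Spp1, Ccl6 and Cd63 did not pass in every fit that left out 1 array, where their adjusted p reached 0.123, 0.224 and 0.191.

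Markers of other myeloid cells were higher in part. Of 20 monocyte markers, the hyaluronan receptor Cd44 (2.77-fold) and the intermediate filament gene Vim (3.19-fold), both also expressed outside monocytes, rose and 18 did not pass. On this list 6 were higher when adjusted over the list alone (median 0.33; camera adjusted p = 6.38e-10, and 0.0115 with an estimated correlation). Of 21 neutrophil markers, Lcn2, the stefin gene Stfa2l1 (2.36-fold, from a control signal of 2.62 ± 0.31 not shown to be above background) and the decoy interleukin 1 receptor Il1r2 (2.29-fold) rose and 18 did not pass, while 5 were higher when adjusted over the list alone (median 0.23; camera adjusted p = 3.18e-06, and 0.0406 with an estimated correlation). None of 13 markers of border-associated macrophages, which line the meninges and vessels, passed over all genes or when adjusted over the list alone. Their median of 0.40 stood above the other genes (camera adjusted p = 1.47e-05, and 0.0229 with an estimated correlation), with Lyve1 at 6.46 and 7.03 and Cbr2 at 6.30 and 6.70 in control and stroke. Of 19 lymphocyte and natural killer cell markers, 0 passed over all genes or when adjusted over the list alone. Their mean signal was 4.65, below the array medians and not shown to be above background. Their median was -0.14, with Nkg7 and Prf1 at -0.19 and -0.14, and the list lay below the other genes at an adjusted p of 0.00242, which was an adjusted p = 0.118 with an estimated correlation and 0.0564 without control replicate 2. Itgam, the gene of CD11b itself, was 1.79-fold higher at 7.01 ± 0.07 against 6.17 ± 0.40 and did not pass (adjusted p = 0.276). Rpl10a was at 10.34 ± 0.15 and 10.42 ± 0.06, and of these 2 genes, 1 was higher when adjusted over their list alone.

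Reactive astrocyte markers, genes induced in astrocytes by injury, had the highest median of the 31 lists tested. Of 17 genes, 11 rose, 0 fell and 6 did not pass, and 16 were higher when adjusted over the list alone (median 1.67; camera adjusted p = 9e-44, and 0.00336 with an estimated correlation). Besides Serpina3n, Timp1, Lcn2 and Vim, the oncostatin M receptor gene Osmr rose 5.86-fold, from 5.54 ± 0.07 to 8.09 ± 0.36 (adjusted p = 0.00331). Of 12 general astrocyte markers, 0 passed over all genes and 2 did when adjusted over the list alone (median 0.30; camera adjusted p = 3.75e-06, and 0.0274 with an estimated correlation); the brightest, Aldoc and Atp1b2, differed by 0.20 and 0.30. Gfap, a further member of that list, was left out because its cluster is shared with Gm39395; that cluster rose 3.54-fold (adjusted p = 0.0139 in a fit of all clusters with a symbol). Among 15 neuron markers 0 passed over all genes or when adjusted over the list alone, with a median of -0.04 (camera adjusted p = 0.615). Snap25 and Syt1 differed by 0.01 and -0.10. Likewise, 0 of 14 oligodendrocyte lineage markers (median 0.03; camera adjusted p = 0.879; Mobp 0.29) and 0 of 16 endothelial and mural markers (camera adjusted p = 0.907; Rgs5 -0.14, Acta2 -0.34) passed in either adjustment. In the endothelial list the median (-0.05) and mean (-0.0051) were below 0 while its test pointed up, since the test is relative to the other genes. Among 6 red blood cell markers 0 passed in either adjustment, with a median of -0.29 and Hba-a2 at -0.25. Their adjusted p of 0.0429 was an adjusted p = 0.281 with an estimated correlation and 0.138, 0.275, 0.352 and 0.0616 without control replicates 1 and 3 and stroke replicates 2 and 3.

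**Figure D3:**
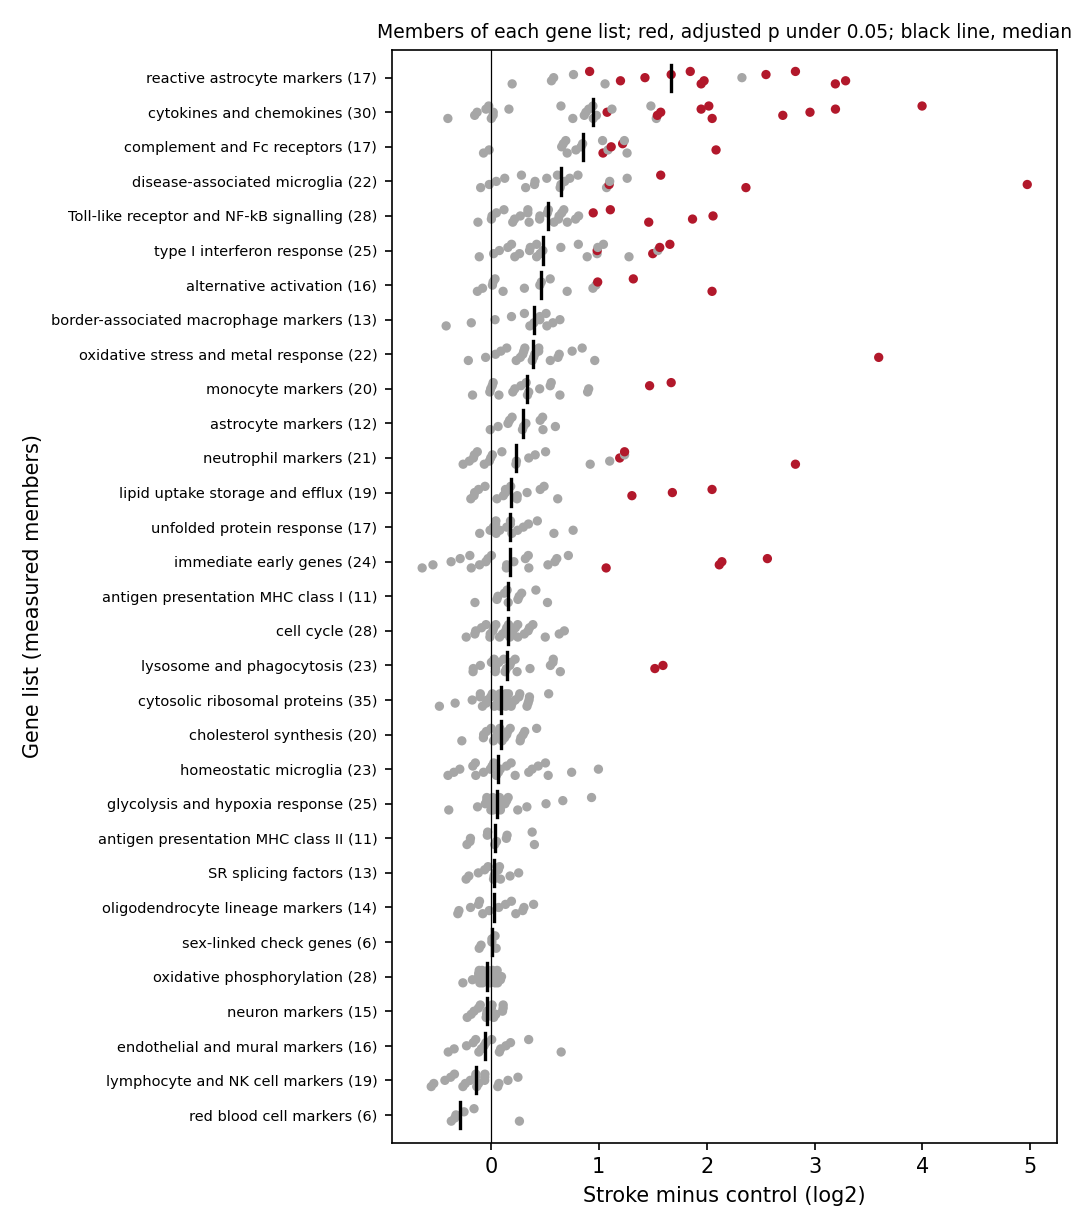
Log2 difference of stroke minus control for every measured member of the 31 gene lists tested, in order of the list median (black line), with members at an adjusted p under 0.05 in red and the number of measured members in parentheses. Reactive astrocyte markers (median 1.67) and cytokines and chemokines (0.95) stand highest, and the neuron, oligodendrocyte and endothelial lists lie around 0.

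Stress, lipid and early response genes changed in a small number of members. Of 24 immediate early genes, Fosl1 (5.91-fold) and Atf3 (4.41-fold), both AP-1 and related transcription factors, Zfp36 (4.34-fold), which destabilises cytokine mRNAs, and Ier3 (2.10-fold) rose and 20 did not pass. When adjusted over the list alone 7 were higher and 1 lower (median 0.18; camera adjusted p = 3.36e-05, and 0.0229 with an estimated correlation). Of 22 oxidative stress and metal response genes Hmox1 alone rose and 21 did not pass, and 8 were higher when adjusted over the list alone (median 0.39; camera adjusted p = 4.17e-14, and 0.0144 with an estimated correlation). Of 19 lipid handling genes, the scavenger receptor Msr1 (4.14-fold), the cholesterol hydroxylase Ch25h (3.21-fold) and the lipid droplet gene Plin2 (2.47-fold) rose and 16 did not pass. On this list 4 were higher when adjusted over the list alone (median 0.18). The camera adjusted p of 5.7e-06 became an adjusted p = 0.0532 with an estimated correlation. Msr1, the cytokine signalling inhibitor Socs3 (2.50-fold) and the interleukin 4 receptor gene Il4ra (1.99-fold) were the 3 of 16 alternative activation genes that rose (13 did not pass). When adjusted over the list alone, 7 were higher (median 0.46; camera adjusted p = 2.85e-09, and 0.0122 with an estimated correlation). Of 23 lysosome and phagocytosis genes, Cd68 (3.02-fold) and the cathepsin gene Ctsc (2.87-fold) rose and 21 did not pass, and 3 were higher when adjusted over the list alone (median 0.14; camera adjusted p = 6.6e-06, and 0.0205 with an estimated correlation). No member of the unfolded protein response list passed over all genes (0 of 17), 2 did when adjusted over the list alone, and Xbp1 and Atf4 differed by 0.19 and 0.25 (median 0.18; camera adjusted p = 0.000111, and 0.0274 with an estimated correlation). Of the 12 genes named here as risen, Fosl1 and Hmox1 stayed past the threshold without each of the 6 arrays in turn, and all 12 stayed higher in stroke.

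In the remaining lists 0 genes passed over all genes or when adjusted over the list alone. Cell cycle genes (28 measured; Pcna 0.36, Ccnb2 0.20) had a median of 0.16, with a camera adjusted p = 0.000136 that was an adjusted p = 0.115 with an estimated correlation. MHC class I genes (11 measured, median 0.16; B2m 0.42, Psmb10 0.07) had an adjusted p of 0.00233, which was an adjusted p = 0.126 with an estimated correlation. MHC class II genes (11 measured; H2-DMa -0.03, H2-Eb1 -0.03) had a median of 0.03 and an adjusted p of 0.42. For glycolysis and hypoxia genes (25 measured, median 0.06; Gapdh 0.06, Gpi1 0.07) the adjusted p of 0.0176 was an adjusted p = 0.155 with an estimated correlation and 0.0654, 0.0826 and 0.0559 without control replicates 2 and 3 and stroke replicate 3. Cholesterol synthesis genes (20 measured, median 0.09; Fdft1 0.27, Hmgcs1 -0.07) went from an adjusted p of 0.0304 to an adjusted p = 0.216 with an estimated correlation and 0.0784, 0.147, 0.101 and 0.103 without control replicates 1 and 2 and stroke replicates 1 and 2. The 35 cytosolic ribosomal protein genes (median 0.10; Rplp1 0.08, Rps6 0.09) went from 0.0304 to an adjusted p = 0.397 with an estimated correlation and 0.0538, 0.371 and 0.304 without control replicates 2 and 3 and stroke replicate 1. Oxidative phosphorylation genes (28 measured, median -0.03, adjusted p = 0.51; Atp5b -0.00043, Cox8a -0.0088) and SR splicing factors (13 measured, median 0.03, adjusted p = 0.879; Srsf5 0.07, Srsf2 0.26) did not stand apart from the other genes. The former lay lower without control replicate 3 (mean -0.14, adjusted p = 0.00627). The splicing factor gene Srsf3 was at 7.88 ± 0.29 and 7.91 ± 0.17.

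Of the 6 sex-linked genes 0 passed over all genes or when adjusted over the list alone (limma). Xist, the X-inactivation transcript of female cells, was at 3.48 ± 0.36 in control and 3.52 ± 0.10 in stroke, and the Y-linked Ddx3y at 8.93 ± 0.22 and 8.94 ± 0.49. Tsix, Uty, Kdm5d and Eif2s3y differed by -0.11, 0.04, -0.09 and 0.0088. Kdm5d was at 6.32 and 6.56 in the control and stroke arrays numbered 2 and between 7.69 and 8.26 in the other 4. The 6 genes had a median of 0.0089 and a mean of -0.02, with the test pointing down (camera adjusted p = 0.907). The labels describe the animals both as males only and as an equal mix of males and females. Over the 6 arrays Ddx3y lay between 8.38 and 9.27 and Eif2s3y between 7.84 and 8.15. These values argue against any array holding RNA of females alone. Xist lay between 3.19 and 3.87 and gave no sign of female RNA. How well Xist is kept in ribosome-bound RNA was not tested, so an array with mice of both sexes is not excluded.

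The authors' deposited table for the same comparison lists 106 transcript clusters higher and 1 lower in stroke at an adjusted p under 0.05, and 183 higher and 13 lower at an unadjusted p under 0.05 and at least 2-fold. All 100 of its adjusted calls that carry a single gene symbol are among the 125 genes found here. It gives Lilrb4a at 22.3-fold, Ccl3 at 15.16-fold and Hmox1 at 11.46-fold, from robust group averages rather than plain means. Across all clusters of that table, which are not independent of each other, the log2 fold in the authors' deposited table correlated with the plain-mean difference at r = 0.858, and at r = 0.984 among the 125 genes.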

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

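All tests in this part concern clusters that the gene comparison did not use, and they were run after that comparison had been seen. Signal was higher in stroke than in control for 2 of 11374 clusters that lack a single symbol or are not in the authors' table, and lower for 0 (limma, fitted over all 41345 clusters, adjusted p under 0.05). At an unadjusted p under 0.05, 295 were higher and 433 lower, and 0 passed when adjusted over these clusters alone. The cluster with the lower adjusted p (0.0149) is not in the authors' table, which supplied the symbols, so its symbol is unknown here. Its mean was 3.38 in control and 5.66 in stroke, a 4.86-fold rise in signal whose control level is not shown to be above background. The other is shared by Gfap, the intermediate filament gene of astrocytes, and the gene model Gm39395. Its mean was 9.30 in control and 11.13 in stroke, a 3.54-fold rise (SE 0.20 on the log2 scale, adjusted p = 0.0467), and its probes cannot assign the signal to either gene. No explanation was tested for either cluster.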

How the results depend on the processing

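Leaving out both arrays numbered 2 was chosen only after the result was seen; all other alternatives were fixed before. The planned use of per-array columns of the authors' workbook was not run, since its sheet holds group averages. Where no reason is given, the cause was not tested.

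Quantile normalization, median centring, both filters, trend and robust eBayes, the mean over clusters and the replicate block gave 121 to 153 higher genes against 124. Array weights gave 214 higher and 3 lower genes, and the replicate block 3 lower. The test without moderation gave 0 higher and 0 lower genes after adjustment, also at 2-fold, and 3 lower at an unadjusted p under 0.05 and 2-fold. The filter at the median signal gave 0 lower genes at 2-fold. Without both arrays numbered 2 there were 70 higher and 0 lower genes, all 70 at least 2-fold, with 57 shared. Leaving out 1 array gave 25 to 73 higher and 0 to 1 lower genes, with the same range at 2-fold; fewer arrays were fitted. Of the 125 genes, 125 kept their sign and 21 stayed past the threshold without each array. Lists above the other genes numbered 22, against 19 with quantile normalization and 18 with the filter at the median signal. Calls lost with both were homeostatic microglia (camera adjusted p = 0.105 and 0.304), cholesterol synthesis (0.115 and 0.123) and cytosolic ribosomal proteins (0.103 and 0.0737). Glycolysis and hypoxia was lost with the filter (0.104). Lists below the other genes numbered 2, against 0 with an estimated correlation, 1 with the filter at the median signal and 1 to 2 without 1 array. With that filter the lymphocyte and natural killer cell list kept too few members for a result, so its call was not tested there. By fry, which does not compare a list with other genes, 0 lists moved lower. Of 24 list calls, 18 held without each array, as did 14 of 44 called named genes. Il1b passed with array weights (1.82, adjusted p = 0.0164).

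All changes of sign were in genes and lists that had not passed, 62 among genes and 19 among lists over all settings. With array weights they were Cst3 0.0082, Snap25 -0.0048, Psmb10 -0.021, Eif2s3y -0.0052, Srsf3 -0.015, Tmem119 -0.087 and Xist -0.15. With quantile normalization they were Atp5b 0.018, Ddx3y -0.00099, Eif2s3y -0.037, Srsf3 -0.015 and the SR splicing factor list -0.012, and with median centring Atp5b 1.83e-05. Without both arrays numbered 2 they were Cst3 0.0095, Cox8a 0.044, Srsf5 -0.086, Eif2s3y -0.079, Srsf3 -0.056, Tmem119 -0.075, Xist -0.15, Uty -0.098, the oligodendrocyte list -0.0054, the endothelial list 0.020 and the SR splicing factor list -0.055. With the filter at the median signal they were the endothelial list 0.010 and the MHC class II list -0.032.

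Leaving out 1 array gave Cst3 -0.16 to 0.16, Nkg7 -0.34 to 0.074, Snap25 -0.062 to 0.085, Rgs5 -0.36 to 0.096, H2-DMa -0.096 to 0.058, H2-Eb1 -0.097 to 0.028, Psmb10 -0.077 to 0.20, Atp5b -0.042 to 0.026, Cox8a -0.17 to 0.082 and Rplp1 -0.022 to 0.20. It gave Rps6 -0.0014 to 0.22, Srsf5 -0.13 to 0.24, Ddx3y -0.16 to 0.29, Eif2s3y -0.075 to 0.080, Rpl10a -0.0010 to 0.15, Srsf3 -0.14 to 0.13, Tmem119 -0.072 to 0.17, Xist -0.096 to 0.25, Uty -0.24 to 0.25 and Kdm5d -0.66 to 0.31. The list means ranged over neuron -0.076 to 0.0086, oligodendrocyte -0.035 to 0.078, endothelial -0.12 to 0.12, oxidative phosphorylation -0.14 to 0.037, SR splicing factor -0.058 to 0.095 and sex-linked -0.20 to 0.095.

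With 3 arrays per group, small differences on top of the background signal of each probe are not resolved.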

Other observations

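The tests on reactive astrocyte markers and on the share of all neuronal RNA were chosen only after the result was seen; the splits, the loss of striatal RNA and both tests on same-numbered arrays were written before. Of the 124 genes that rose, 73 are in no list, and those described here were chosen after their values were seen. Among them, the cytokine gene Il11 rose 3.93-fold, the receptor genes Tnfrsf1a 2.99-fold, Il1r1 2.81-fold, Tnfrsf12a 2.75-fold and Il13ra1 2.19-fold, and the alarmin gene Il33 2.64-fold. The fatty acid receptor gene Gpr84 rose 3.87-fold, the nucleotide receptor genes P2ry6 and P2ry2 3.12-fold and 2.72-fold and the chemokine receptor gene Ccr1 2.06-fold. The Toll-like receptor relative Cd180 rose 3.18-fold and the proton sensor gene Gpr65 2.73-fold, but neither passed with the replicate block (blocked adjusted p = 0.061 and 0.0796). The metalloproteinase gene Mmp3 rose 3.50-fold, the protease inhibitor gene A2m 3.81-fold and the urokinase receptor gene Plaur 1.91-fold.

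Msn, which links actin to the membrane, rose 3.76-fold, Anxa2 3.08-fold and the tubulin gene Tubb6 4.09-fold. The stress genes Hspa1a and Cdkn1a rose 4.45-fold and 3.73-fold, the transcription factor gene Runx1 2.49-fold, and the acute phase gene Saa3 3.48-fold. The transcription factor gene Cebpd rose 2.54-fold and did not pass with the replicate block (blocked adjusted p = 0.0718). Without the block, adjusted p values of the genes named here lay under 0.05, and Msn, Anxa2, Mmp3 and Tnfrsf1a stayed past the threshold without each of the 6 arrays. Hspa1a has a near-identical neighbour, Hspa1b, and the signal of its probes was not separated between them.

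The 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05: the real split gave 125 genes and the highest other 0, so 1 split gave as many. The homeostatic microglia list passed the main test (camera adjusted p = 0.0429) but not with an estimated correlation (adjusted p = 0.397). A fry test for changes of its members in either direction gave an adjusted p of 0.0122. The tests planned for a difference in this list were not run. Carried-over RNA of neurons and glia and a changed share of microglia were therefore not tested for it.

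Of 17 reactive astrocyte markers 11 rose, with a median of 1.67 over all 17. A larger share of astrocyte RNA would raise general astrocyte markers by a like amount, but their median was 0.297 (12 genes; permutation p = 0.00274 for the difference, genes not being independent). The cluster shared by Gfap and Gm39395 (1.82) lay above the median of these 12 genes and that of Glul (0.0038) below it. The signal of the former cannot be assigned to either gene. Adding both could not move the median (0.30 for 14 markers), so the permutation p of 0.00264 with them is no separate support. The median of the 12 genes argues against a larger astrocyte share as the whole cause, although the cluster shared by Gfap rose more than the reactive median. RNA of neutrophils and monocytes stays open: the 14 reactive members held by no neutrophil, monocyte or cytokine list had a median of 1.31, but these cells may express them as well. A change within astrocytes, or expression of these genes by the tagged cells, may also underlie the rise, and both stay open.

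Striatal projection neuron markers, from a list written before its test and without 3 genes that had been seen, among them Pde10a (-0.64) and Adora2a (-0.82), had a median of -0.368 against -0.0365 for general neuron markers (permutation p = 1e-04 across genes, which are not independent). All 21 lay below 0, with 0 past the threshold (limma, also with the block) and 8 lower at an unadjusted p under 0.05, and the difference of medians ranged from -0.44 to -0.21 without 1 array. Across arrays, the mean of striatal minus general markers was -1.93 ± 0.19 in control and -2.27 ± 0.24 in stroke (SD, n = 3). The groups overlapped, with control replicate 2 at -2.145 and stroke replicates 1 and 3 at -2.142 and -2.124. An exact permutation over arrays, which does not use their numbers, gave p = 0.3 (two-sided, smallest possible 0.1). In 3 of 3 same-numbered pairs the value was lower in stroke, with differences of -0.41 to -0.28. The labels do not state a pairing. The general neuron median of -0.0365 gave no sign of a large fall in the share of all neuronal RNA. A smaller fall stays open, since bright signals (list mean 11.23) on arrays scaled before deposit may understate it. Chance stays open for the lower striatal markers, since the permutation over arrays gave p = 0.3. If the difference is real, loss of striatal neuron RNA may account for it, while a fall in expression and a difference in dissection stay open.

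Same-numbered arrays of the groups deviated together, with correlations across genes of 0.299, 0.576 and 0.39. Unlike numbers gave -0.46 to 0.237, and the 3 deviations of a group sum to 0, so the 3 matches are not independent. After quantile normalization and removal of the signal trend the lowest same-number correlation was 0.273. As deposited, the deviations of the control and stroke arrays numbered 2 both correlated with log10 gene length (r = -0.333 and -0.246). After removal of the gene length trend, for the 87.2% of genes with a length, the lowest same-number correlation was 0.283. The pair numbered 2 then gave 0.535. The correlations that remained argue against either trend as the whole cause. Shared handling or a shared day of same-numbered arrays may be behind it; the labels do not state either, and no biological explanation was tested.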
